A study of Mus musculus with 8 samples.

How the data were processed

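RNA from the nucleus accumbens of male C57BL/6 mice given morphine or saline was profiled in 8 libraries, 4 per group. Per the labels' protocols, total RNA was extracted with Trizol, full-length cDNA was made from an oligo-dT primer with a template-switching oligonucleotide, amplified by PCR and sequenced on an Illumina NovaSeq. The protocol names no molecular identifiers and no strand marking, so copies made by PCR are not told apart, and reads of overlapping antisense genes cannot be separated. Dose, schedule, and the time between the last injection and dissection are not given in the sources used here.

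The authors deposited 1 table of FPKM values for the whole series, per the file headers 1 column per library, rounded to 2 decimals, with gene symbols, KEGG and Gene Ontology annotation. Per the submitters' processing notes, fastp 0.18.0, Bowtie2 2.2.8, HISAT2, StringTie 1.3.1 and RSEM were used with the mouse build mm10; their order and roles, the annotation release and the strand setting are not given in the sources used here. FPKM divides out library size and transcript length, so a transcript class that takes a larger share of a library lowers the values of all other genes in it. Because the mitochondrial share differed between the groups, an added setting removed those genes and rescaled the rest.

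Whether the values keep whole reads was checked on 6755 low values: 19.6% were whole multiples of the gene's smallest value within 0.1, where 20% is the share for evenly spread remainders. The check compared values across libraries, whose unknown depths scale FPKM differently, and the values are rounded. It therefore cannot decide whether whole reads are kept. No depth was recovered, so no count model was used, and no counting interval is given. The table holds 22337 genes with Ensembl identifiers, of which 22232 matched GENCODE M21 (GRCm38, the assembly that mm10 names) and 105 did not; symbols and coordinates (1-based) were taken from that annotation, since the table's own symbols were missing for 1246 genes. All genes named here are printed under their GENCODE symbol. No pair of libraries was a copy of another: between 0.13 and 0.28% of the values were identical between any pair. Sex-linked genes were listed as a check of the male sex in the labels and were not tested as a list. Their values are not given here.

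The comparison was morphine against saline over all 8 libraries, without a block. Values were taken as log2(FPKM + 1), and 12536 genes with an FPKM of at least 1 in at least 4 libraries were tested with limma 3.58.1 in R 4.3.3 (linear model and empirical Bayes with a mean-variance trend, two-sided, Benjamini-Hochberg adjusted p under 0.05). Gene lists for neuron classes, glia, vessels, neighbouring regions, signalling, stress, immune, synaptic and metabolic genes were fixed before the data were examined. The 33 lists with at least 3 tested members were tested with camera (preset correlation 0.01, trend in the variance, Benjamini-Hochberg over the lists), with the correlation estimated, and with fry, which asks whether a list's own genes move one way and not whether they differ from other genes. The mean of each list per library was also compared by an exact permutation test over 70 assignments of the 8 libraries. A list's counts of rising and falling members are those past the threshold over all genes. KEGG pathways and Gene Ontology terms of 10 to 300 tested genes, as the table assigns them, were tested with camera, and genes past the threshold by a one-sided Fisher exact test against the tested genes with that annotation.

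The genes named follow a rule written before the data were examined: the 12 largest rises and 12 largest falls among genes past the threshold whose groups do not overlap and whose mean FPKM is at least 1 in a group, leaving out predicted genes and pseudogenes; the 2 to 4 members with the smallest p of each list that passes and of the opioid, dopamine, immediate early, glucocorticoid, D1 and D2 lists; 10 genes of the opioid, dopamine and stress systems whatever their outcome; and the 3 genes with the smallest p of a pathway that passes. Whether 2 or 4 members of a list were named, and that pathway genes were named only for the 3 pathways with the smallest p in each direction, was settled after the values were seen. Some genes that fall under the rule are not reported here. A gene outside the rule is said to have been chosen after its values were seen. Acin1, which falls under the rule, had an adjusted p at the threshold after rounding and is given here only as 0.526 ± 0.121 (log2, SE).

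The gene and list tests were tested on simulated data for 12536 genes with 200 changed genes in each of 10 runs: 77.4% of genes changed by 1 on the log2 scale and 96.6% of those changed by 2 were found, with 4.7% false calls, and 0 of 33 lists were called where nothing had changed. The simulated genes vary independently. On the real libraries, splits with 2 saline and 2 morphine libraries on each side called between 4 and 13 lists with the same test. Alternatives were quantile and median-ratio scaling, other pseudocounts (0.1 and 5), other filters on low values, robust and weighted limma fits, other thresholds, the replicate number as a block, leaving out each library, and, as a covariate, the mean of each list of glia, vessels, ependyma or neighbouring regions that followed the first principal component (cortical, septal, endothelial, mural and ependymal). Other lists that followed it, such as D1, D2, dopamine, GABA, interferon and cytoskeleton, were not run as covariates. The striatal covariate, the removal of mitochondrial genes and the separate reading without saline replicate 3 were chosen after seeing the data. That library stood apart from the others, which does not show that it is the faulty one. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.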

Results

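The data were RNA-seq profiles of the nucleus accumbens, a ventral part of the striatum that receives dopamine input and takes part in reward, from male C57BL/6 mice given morphine or saline. Morphine is an opioid that acts mainly on the mu opioid receptor. There were 4 morphine and 4 saline libraries, and the series asks how chronic morphine exposure changes the transcriptome of this region. The deposited values were FPKM (fragments per kilobase of transcript, scaled to the number of mapped fragments) for 22337 genes. They summed to between 480003.6 and 540104.1 per library, and between 12287 and 12655 genes reached an FPKM of 1. Read depth per library is unknown, because FPKM carries no library total. The labels do not say that the replicates were separate animals, so the p-values measure the spread between these libraries, which may be technical. Fold changes are differences of log2(FPKM + 1), morphine minus saline, and understate the change of genes near an FPKM of 1. Unless stated otherwise, p-values of single genes are limma's, adjusted by Benjamini-Hochberg over all genes tested.

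Genes of striatal projection neurons made up most of the largest losses in the morphine libraries, and Tfap2d, Oxtr and Nr4a2 had the largest rises under the naming rule. Of 12536 genes tested, 316 passed, 130 higher and 186 lower with morphine, with a smallest adjusted p of 0.0159. At an unadjusted p under 0.05 there were 2526 genes, where chance gives 627. In 315 of the 316 genes all 4 morphine values lay on one side of the 4 saline values. The genes were called on these same values, so this count adds no support to the calls. That arrangement was seen in 12.66% of all tested genes and arises by chance in 2.86%. A change of at least 1 on the log2 scale was reached by 117 of the genes, 36 higher and 81 lower. The number of genes depended on single libraries. Without saline replicate 2, morphine replicate 3 or morphine replicate 4, limma called 0 genes (2005, 1953 and 2136 at an unadjusted p under 0.05). Without saline replicate 1 it called 75, without morphine replicate 1 it called 102, and without morphine replicate 2 it called 70. Without saline replicate 3 it called 296, of which 208 were among the 316. The named genes Tfap2d, Fibcd1, Aldoc, Slc2a1, Nefl, Aox1 and Pqbp1 then missed the threshold (adjusted p between 0.0512 and 0.0737). With mitochondrially encoded genes removed and the rest rescaled, a setting chosen after the data were seen, 77 genes were higher and 211 lower, so that the share of higher calls was 26.7% where it had been 41.1%.

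The 12 largest rises under the naming rule included transcription factor genes. Tfap2d, one of them, went from 0.743 ± 0.617 FPKM in saline to 6.17 ± 4.08 in morphine (SD, n = 4 each; log2 change 1.91 ± 0.43 SE, adjusted p = 0.0471). Nr4a2, an orphan nuclear receptor that is also an immediate early gene, went from 5.51 ± 2.88 to 19.0 ± 1.51 FPKM (SD, n = 4 each; adjusted p = 0.0281). Nfil3, a repressor of clock-controlled genes, went from 4.37 ± 0.245 to 13 ± 3.12 FPKM (SD, n = 4 each; adjusted p = 0.0159). Oxtr, the oxytocin receptor gene (ENSMUSG00000049112, chromosome 6, 112473683 to 112489943, minus strand, GRCm38), went from 4.06 ± 2.87 to 15.0 ± 5.26 FPKM (SD, n = 4 each; adjusted p = 0.0391). Kcng1, a voltage-gated potassium channel subunit gene, rose by 1.41 ± 0.27 (log2, SE) and Fibcd1, a chitin-binding membrane protein gene, by 1.43 ± 0.32. The Ras-like genes Rasl11a and Rasl11b rose by 1.40 ± 0.21 and 1.26 ± 0.24. Cdc25c and Psrc1, which act in cell division, rose by 1.58 ± 0.25 and 1.57 ± 0.24, and Ldoc1 rose by 1.41 ± 0.25. Obp1a, an odorant-binding protein gene with close relatives that may share reads, was listed at a mean of 0.343 FPKM in saline and 3.56 in morphine (log2 change 1.70 ± 0.35 SE, adjusted p = 0.0391). Saline replicate 3 held the lowest saline value of Tfap2d (0 FPKM), Oxtr (1.35), Nr4a2 (1.76), Cdc25c, Psrc1, Rasl11a and Rasl11b, and not of the others. Without it the 12 log2 changes lay between 1.07 and 1.93. With the mean of the striatal list as a covariate they lay between 0.56 (Nr4a2) and 2.54 (Obp1a), with Oxtr at 0.76. Those of Obp1a, Kcng1 and Nfil3 were then larger and the others smaller.

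Markers of striatal medium spiny neurons fell with morphine. In the list of striatal neuron genes 6 of 23 tested members fell, none rose and 17 did not pass; the median log2 change was −1.19 (camera, preset correlation, adjusted p = 8.25e-10). With an estimated correlation the adjusted p of that list was 0.264. Adjusted over the list alone, 17 members were lower and 2 higher. Ppp1r1b (ENSMUSG00000061718, chromosome 11, 98348404 to 98357796, plus strand, GRCm38), whose product relays dopamine signals in these neurons, went from 608.8 ± 563.9 to 80.1 ± 25.6 FPKM (SD, n = 4 each; adjusted p = 0.0247; 1454.6 in saline replicate 3 and 318.2 to 341.0 in the other saline libraries). Foxp2, a transcription factor gene, and Syndig1l fell by 2.63 ± 0.34 and 1.96 ± 0.32 (log2, SE). The Ras family gene Rasd2 fell by 2.29 ± 0.51, the sodium channel subunit gene Scn4b by 3.60 ± 0.58 and Lrrc10b by 2.59 ± 0.37. Without saline replicate 3 these 6 genes still passed, with log2 changes between −2.962 and −1.595.

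Markers of both classes of medium spiny neuron were lower as lists. Of 8 tested markers of the direct pathway class, which carries the D1 dopamine receptor, 4 fell, with a median log2 change of −2.06 (camera adjusted p = 7.37e-05; adjusted p = 0.264 with an estimated correlation; 5 lower adjusted over the list alone). Drd1 itself (ENSMUSG00000021478, chromosome 13, 54051183 to 54055705, minus strand) went from 38.0 ± 32.9 to 3.86 ± 2.24 FPKM (SD, n = 4 each; adjusted p = 0.0207; 87.2 in saline replicate 3 and 19.9 to 23.4 in the other saline libraries). Isl1, a transcription factor gene of this class, fell by 2.27 ± 0.34 and the dynorphin precursor gene Pdyn by 2.87 ± 0.61 (log2, SE), and without saline replicate 3 their log2 changes were −1.94 and −2.14. Of 8 tested markers of the indirect pathway class, which carries the D2 receptor, 2 fell, with a median of −1.63 (camera adjusted p = 0.0055; adjusted p = 0.419 with an estimated correlation; 5 lower and 1 higher adjusted over the list alone). Without saline replicate 3 that median was −1.03 and the list still passed. The members that fell were the adenosine receptor gene Adora2a, from 54.1 ± 75.7 to 1.97 ± 1.61 FPKM (SD, n = 4 each; adjusted p = 0.0406; 167.4 in saline replicate 3 and 12.1 to 23.5 in the other saline libraries), and the enkephalin precursor gene Penk, from 733.5 ± 635.1 to 121.7 ± 71.3 FPKM (SD, n = 4 each; adjusted p = 0.0435; 1683.4 in saline replicate 3 and 353.3 to 467.1 in the other saline libraries). Drd2 had 7.95 ± 10.1 FPKM in saline and 0.368 ± 0.155 in morphine (SD, n = 4 each) and did not pass (limma adjusted p = 0.0642), but it passed without saline replicate 3, which had 23.1 FPKM (log2 change −1.48, adjusted p = 0.01).

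**Figure D1:**
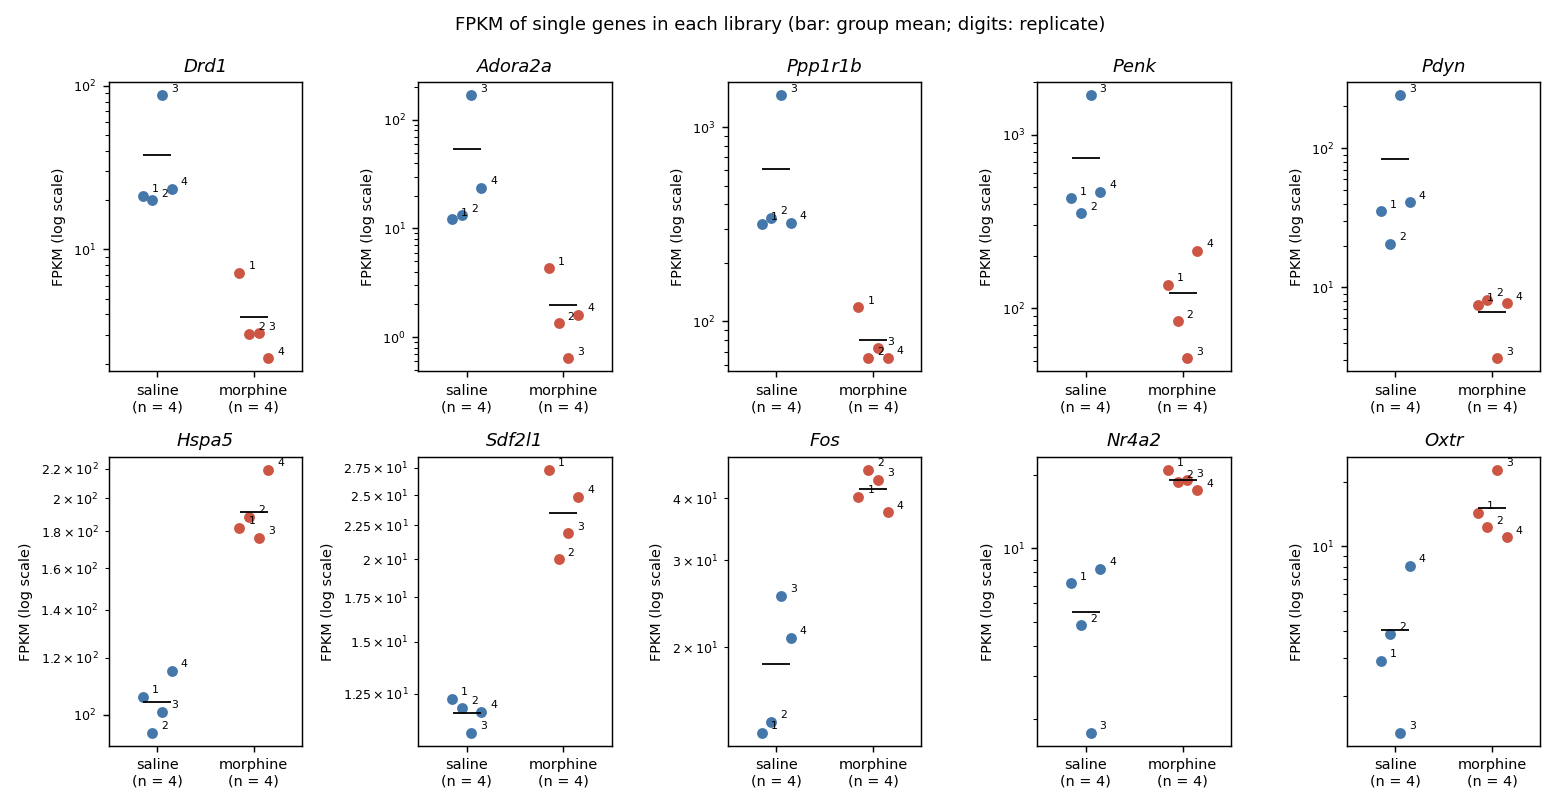
FPKM on a log axis of 5 genes of striatal neurons (top row) and 5 genes that were higher with morphine (bottom row), one point per library with its replicate number and a bar at the group mean. Saline replicate 3 lies far above the other saline libraries in the top row (Drd1 at 87.2 FPKM against 19.9 to 23.4), and all 4 morphine libraries lie below every saline library there.

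The saline libraries differed among themselves in the same genes. The mean level of the striatal neuron list was 6.78 in saline replicate 3, between 5.17 and 5.27 in the other saline libraries and between 4.25 and 4.34 in the morphine libraries (log2 scale). Without saline replicate 3 the median log2 change of the list was −0.74 and the list still passed (camera adjusted p = 1.4e-14). That reading leaves out the library with the highest striatal and the lowest cortical list mean. Because the nucleus accumbens is part of the striatum, these values do not show whether that library or the others depart from the intended tissue. With the mean of the striatal list as a covariate, a setting chosen after the data were seen, limma called 2 genes, with 1383 at an unadjusted p under 0.05. All 316 genes kept their direction; the median ratio of their log2 changes to those without the covariate was 0.70 and that of their SE 1.59.

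Markers of cortical glutamatergic neurons moved the opposite way to the striatal genes. In that list 1 of 15 tested members rose, with a median log2 change of 0.55 (camera adjusted p = 0.000686; adjusted p = 0.442 with an estimated correlation; 1 higher adjusted over the list alone). Without saline replicate 3 the median was 0.29 (camera adjusted p = 0.015). The member that rose was Neurod1, a neuronal transcription factor gene, at 2.02 ± 0.978 FPKM in saline and 5.41 ± 1.07 in morphine (SD, n = 4 each; adjusted p = 0.0471). Neurod2 had a log2 change of 1.32 ± 0.42 (SE) and did not pass (adjusted p = 0.121), but it passed without saline replicate 3 (0.80, adjusted p = 0.0389). The vesicular glutamate transporter gene Slc17a7, chosen after its values were seen, had 19.6 FPKM in saline replicate 3, between 90.8 and 98.0 in the other saline libraries and between 105.8 and 139.5 in the morphine libraries (limma adjusted p = 0.307). With the striatal covariate the median of the cortical list changed sign, to −0.41, and the list passed in that direction (camera adjusted p = 8.23e-06). Markers of septum and hypothalamus, which lie close by, were lower: 2 of 9 tested members fell. The neurotensin gene Nts fell by 1.99 ± 0.24 and Ecel1 fell by 2.14 ± 0.46 (−1.59 without saline replicate 3; log2, SE; list median −0.42, camera adjusted p = 0.0142, adjusted p = 0.264 with an estimated correlation; 3 lower and 1 higher adjusted over the list alone).

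Chaperone genes of the endoplasmic reticulum and heat shock genes rose with morphine. Of 30 tested members 7 rose and none fell, with a median log2 change of 0.26 (camera adjusted p = 8.25e-10; fry adjusted p = 0.00171). With an estimated correlation the adjusted p was 0.179, and adjusted over the list alone 11 members were higher. Hspa5, the main chaperone of the endoplasmic reticulum (ENSMUSG00000026864, chromosome 2, 34771970 to 34777547, plus strand, GRCm38), went from 104.1 ± 8.68 to 191.6 ± 19.1 FPKM (SD, n = 4 each; log2 change 0.87 ± 0.11 SE, adjusted p = 0.0159). Sdf2l1, from the same compartment, went from 11.7 ± 0.574 to 23.5 ± 3.23 FPKM, and the disulfide isomerase gene Pdia6 from 60.6 ± 3.19 to 98.8 ± 4.20 (SD, n = 4 each; adjusted p = 0.0159 for each). Manf, a secreted stress-induced factor, rose by 0.71 ± 0.10 (log2, SE). Hspa1a, a cytosolic heat shock gene nearly identical to Hspa1b so that reads may be shared, rose by 1.12 ± 0.17. The mean level of the list lay between 5.42 and 5.54 in saline and between 5.78 and 5.85 in morphine. The list did not pass with the mean of the endothelial list as a covariate (median 0.14, camera adjusted p = 0.138).

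Immediate early genes, which neurons switch on after activity, rose in the same libraries. Of 26 tested members 7 rose and none fell, with a median log2 change of 0.52 (camera adjusted p = 3.19e-08; adjusted p = 0.207 with an estimated correlation; fry adjusted p = 0.0165). Adjusted over the list alone, 13 members were higher. Fos (ENSMUSG00000021250, chromosome 12, 85473890 to 85477273, plus strand) went from 18.5 ± 5.70 to 41.7 ± 3.60 FPKM (SD, n = 4 each; log2 change 1.18 ± 0.19 SE, adjusted p = 0.0207). The nuclear receptor gene Nr4a3 rose by 0.99 ± 0.15 and the phosphatase gene Dusp6 by 0.84 ± 0.12 (log2, SE). Fosb, whose stable protein product accumulates in the striatum after repeated drug exposure, had 2.75 ± 0.916 FPKM in saline and 5.71 ± 1.66 in morphine (SD, n = 4 each) and did not pass (adjusted p = 0.0719), but it passed without saline replicate 3 (log2 change 0.99, adjusted p = 0.0382).

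**Figure D2:**
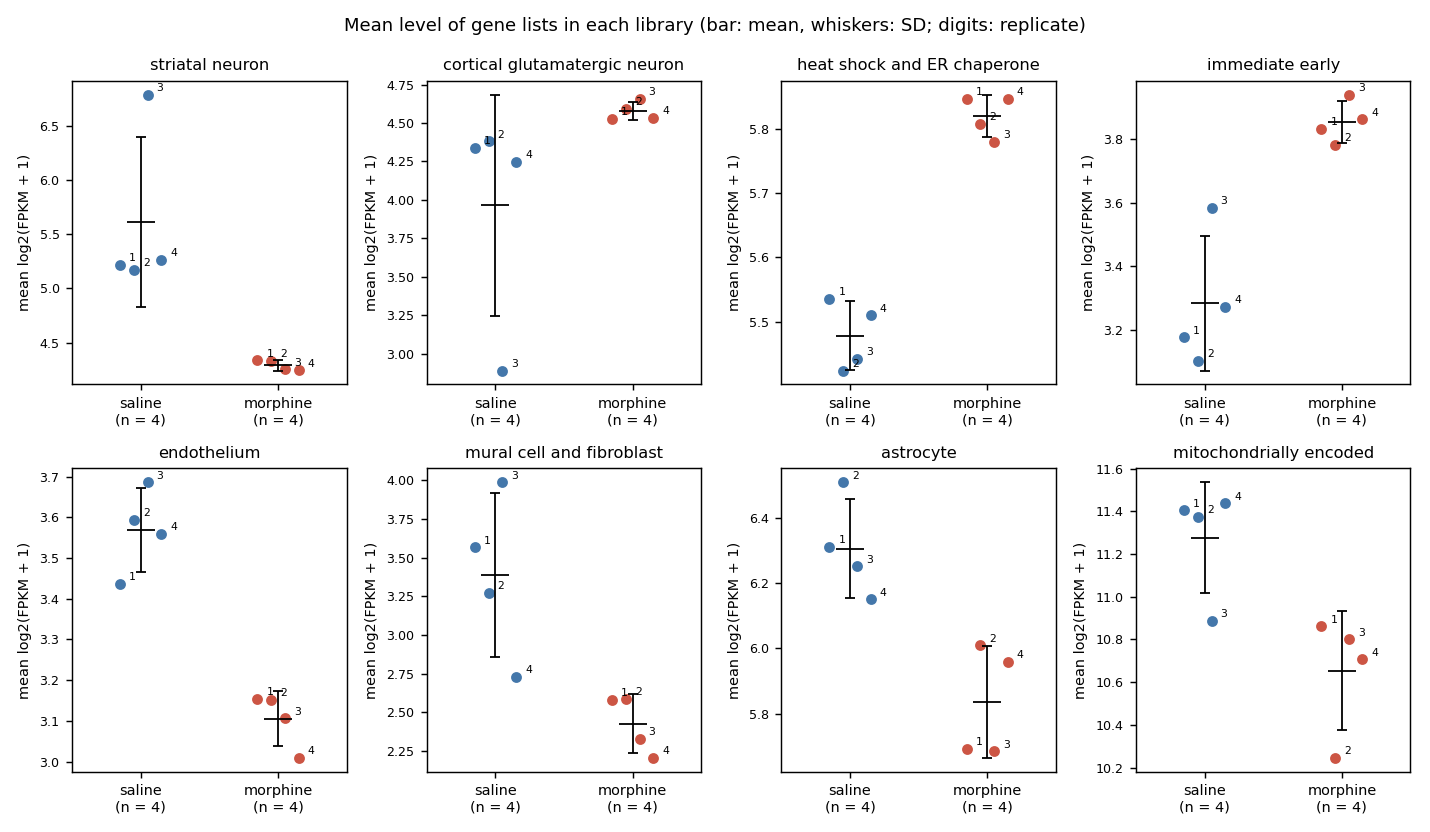
Mean log2(FPKM + 1) of 8 gene lists in each library, with the group mean (bar) and SD (whiskers). Saline replicate 3 is highest for striatal neuron genes (6.78) and lowest for cortical genes (2.89), whereas the 4 morphine libraries lie between 5.78 and 5.85 for heat shock and chaperone genes, above every saline library.

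Vessel and astrocyte genes fell. In the endothelial list 4 of 18 tested members fell and none rose, with a median log2 change of −0.47 (camera adjusted p = 1.86e-09; adjusted p = 0.179 with an estimated correlation; 12 lower adjusted over the list alone). Ly6c1 went from 58.1 ± 3.87 to 34.0 ± 2.33 FPKM (SD, n = 4 each; adjusted p = 0.0159). The glucose transporter gene Slc2a1 and the organic anion transporter gene Slco1a4 of the blood-brain barrier fell by 0.46 ± 0.10 and 0.79 ± 0.13 (log2, SE). Ly6a, which is closely related to Ly6c1 so that reads may be shared, fell by 0.99 ± 0.16. Among 16 tested genes of mural cells and fibroblasts 3 fell, with a median of −0.98 (camera adjusted p = 8.25e-10; adjusted p = 0.264 with an estimated correlation; 10 lower adjusted over the list alone). Vtn fell by 1.00 ± 0.16 and the matrix protein gene Mgp by 1.77 ± 0.31 (log2, SE), and this list did not pass with the striatal covariate (median −0.25, camera adjusted p = 0.0661). Among 20 tested astrocyte genes 4 fell, with a median of −0.43 (camera adjusted p = 1.09e-08; adjusted p = 0.264 with an estimated correlation; 10 lower adjusted over the list alone). The neurotensin receptor gene Ntsr2 went from 222.6 ± 23.7 to 124.3 ± 12.2 FPKM (SD, n = 4 each; adjusted p = 0.0165). The bicarbonate transporter gene Slc4a4 and the glycolytic gene Aldoc fell by 1.29 ± 0.25 and 0.63 ± 0.14 (log2, SE). Outside these lists Myoc, a secreted glycoprotein gene, fell by 2.78 ± 0.50.

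Other non-neuronal lists were also lower. None of 22 oligodendrocyte and myelin genes passed singly, but all had negative changes, with a median of −0.33 (camera adjusted p = 2.3e-05; adjusted p = 0.442 with an estimated correlation; 0 adjusted over the list alone). Without morphine replicate 3 that median was −0.18 and the list still passed. The smallest p among them belonged to Myrf (−0.54 ± 0.15, adjusted p = 0.0768) and Aspa (−0.44 ± 0.13, adjusted p = 0.107). In the ependyma and choroid plexus list 1 of 6 fell, Clic6 by 1.38 ± 0.23 (median −0.92, camera adjusted p = 0.0142, adjusted p = 0.287 with an estimated correlation; 2 lower adjusted over the list alone), and Kcnj13 did not pass (adjusted p = 0.0741; 0.0394 without saline replicate 4). Without saline replicate 3 the median of this list was −0.55 and it still passed. Only 6 of its 19 listed genes were tested. Without a filter on low values its median was −0.179 and it passed (camera adjusted p = 0.0073), so the size of its fall depended on the filter. At an FPKM of 5 too few members were left to test it. In the blood list 2 of 8 fell, the neutrophil genes S100a8 by 2.71 ± 0.52 and S100a9 by 1.89 ± 0.41 (log2, SE; median −0.72, camera adjusted p = 0.0137, adjusted p = 0.442 with an estimated correlation; 3 lower and 1 higher adjusted over the list alone). That list did not pass without saline replicate 1 (camera adjusted p = 0.0773) or without morphine replicate 4 (camera adjusted p = 0.0779). In the interferon list 3 of 18 fell, among them the antigen presentation gene H2-K1 by 0.69 ± 0.11 and Ifitm3 by 1.29 ± 0.23, both from families whose members may share reads (median −0.36, camera adjusted p = 0.000781, adjusted p = 0.264 with an estimated correlation; 6 lower and 1 higher adjusted over the list alone). None of these 4 lists passed with the striatal covariate: the camera adjusted p was 0.138 for oligodendrocyte, 0.0569 for interferon, 0.0569 for blood and 0.696 for ependyma and choroid plexus genes, whose median changed sign to 0.06.

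Mitochondrially encoded transcripts took a smaller share of the FPKM total in every morphine library. That share was 10.9, 12.2, 9.09 and 12.6% in the saline libraries and 7.94, 6.09, 7.55 and 7.58% in the morphine libraries. In this list 1 of 13 fell, mt-Co1 by 0.76 ± 0.15 (log2, SE; median −0.59, camera adjusted p = 2.23e-08, adjusted p = 0.264 with an estimated correlation; 11 lower adjusted over the list alone), and mt-Nd4 missed the threshold (−0.65 ± 0.15, adjusted p = 0.0507; 0.0197 without saline replicate 3). Ribosomal protein genes were slightly higher as a list (median 0.16, 0 of 75 passing singly or adjusted over the list alone, camera adjusted p = 0.000346, adjusted p = 0.697 with an estimated correlation). The smallest p among them belonged to Rps15a (0.49 ± 0.19, adjusted p = 0.192) and Rps7 (0.36 ± 0.15, adjusted p = 0.21). The axon cytoskeleton list had a median of 0.24 with 2 of 23 members higher and 1 lower (camera adjusted p = 0.0205, adjusted p = 0.548 with an estimated correlation; 2 higher and 2 lower adjusted over the list alone). The tubulin gene Tubb2a rose by 0.64 ± 0.15 and the neurofilament gene Nefl fell by 0.77 ± 0.17. Neither of these lists passed without saline replicate 3 (camera adjusted p = 0.0841 and 0.167) or with quantile normalization (camera adjusted p = 0.0956 and 0.105), and the cytoskeleton list did not pass without morphine replicate 1 (camera adjusted p = 0.0788) or with array weights (0.0822) either. With a filter at an FPKM of 5 the cortical, blood and cytoskeleton lists did not pass (camera adjusted p = 0.0537, 0.153 and 0.074).

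Genes of the opioid system did not move one way. Of 22 tested members 2 rose and 4 fell, and the list did not pass (camera adjusted p = 0.852). Camera placed it lower, as did its mean log2 change of −0.23, whereas its median was 0.15 (0.005 without saline replicate 3 and 0.06 without morphine replicate 2). Adjusted over the list alone the counts were 2 and 4 as well. Rgs20, a regulator of G protein signalling, went from 26.1 ± 4.05 to 12.7 ± 0.85 FPKM (SD, n = 4 each; adjusted p = 0.0159). Kcnj9, a G protein-gated potassium channel gene, rose by 0.81 ± 0.15 (log2, SE). Penk and Pdyn fell as given above and belong to the striatal neuron classes too. Of the receptor genes, Oprm1 (mu) had 1.65 ± 1.33 FPKM in saline and 0.955 ± 0.195 in morphine (SD, n = 4 each; adjusted p = 0.614), and Oprk1 (kappa) had 8.15 ± 8.16 and 2.93 ± 1.04 (SD, n = 4 each; adjusted p = 0.359). Saline replicate 3 held the highest value of each (3.48 and 20.1 FPKM), and without it the log2 changes went from −0.31 to −0.009 and from −0.87 to −0.34. Oprd1 (delta) was below the filter and not tested. The dopamine signalling list was lower, with 2 of 12 members falling, Drd1 and Ppp1r1b (median −0.35, camera adjusted p = 2.39e-05, adjusted p = 0.264 with an estimated correlation; 5 lower adjusted over the list alone). All 5 of these lower members are also in the striatal, D1 or D2 lists, so this list is not a result separate from the fall of striatal markers. Some of them are in the striatal list, whose mean served as a covariate.

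Glucocorticoid-responsive genes were lower as a list, with 1 of 24 falling and a median log2 change of −0.25 (camera adjusted p = 0.00369, adjusted p = 0.264 with an estimated correlation; 6 lower and 2 higher adjusted over the list alone). The member that fell was Slc2a1, which the endothelial list holds as well, and Tsc22d4 did not pass (−0.54 ± 0.13, adjusted p = 0.062; 0.0472 without saline replicate 3 and 0.0387 without saline replicate 4). The glucocorticoid targets Fkbp5 and Sgk1 had log2 changes of −0.19 ± 0.19 and −0.25 ± 0.17 (SE; limma adjusted p = 0.618 and 0.44), and that of Fkbp5 was −0.07 without saline replicate 3. In the GABA signalling list 1 of 20 fell, the receptor subunit gene Gabrd by 1.15 ± 0.22 (median −0.26, camera adjusted p = 0.0165, adjusted p = 0.264 with an estimated correlation; 4 lower and 1 higher adjusted over the list alone). Gad2, which makes GABA, did not pass (−1.13 ± 0.32, adjusted p = 0.087).

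In all, 20 of 33 fixed lists passed with camera's preset correlation, 5 higher and 15 lower, and 0 passed with an estimated correlation, the smallest adjusted p being 0.179. With the striatal covariate 10 lists passed with the preset correlation. Of the 20, 6 kept call and direction (heat shock and chaperone, immediate early, endothelium, astrocyte, mitochondrially encoded and glucocorticoid), 2 passed in the opposite direction (cortical and ribosomal), 11 no longer passed (D1, D2, dopamine, GABA, septal, mural, ependymal, oligodendrocyte, blood, interferon and cytoskeleton), and the striatal list itself was not tested. The other 2 lists that passed, cAMP pathway (higher) and microglia (lower), were not among the 20. Of the lists, 6 passed with fry: heat shock and chaperone, endothelium, immediate early, astrocyte, mural cell and fibroblast, and mitochondrially encoded genes. The mean level of 13 lists did not overlap between the 4 morphine and 4 saline libraries. Each of these had p = 0.0286 in an exact two-sided permutation test over 70 assignments, the smallest that 4 against 4 allows, and an adjusted p of 0.0725 over the 33 lists.

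**Figure D3:**
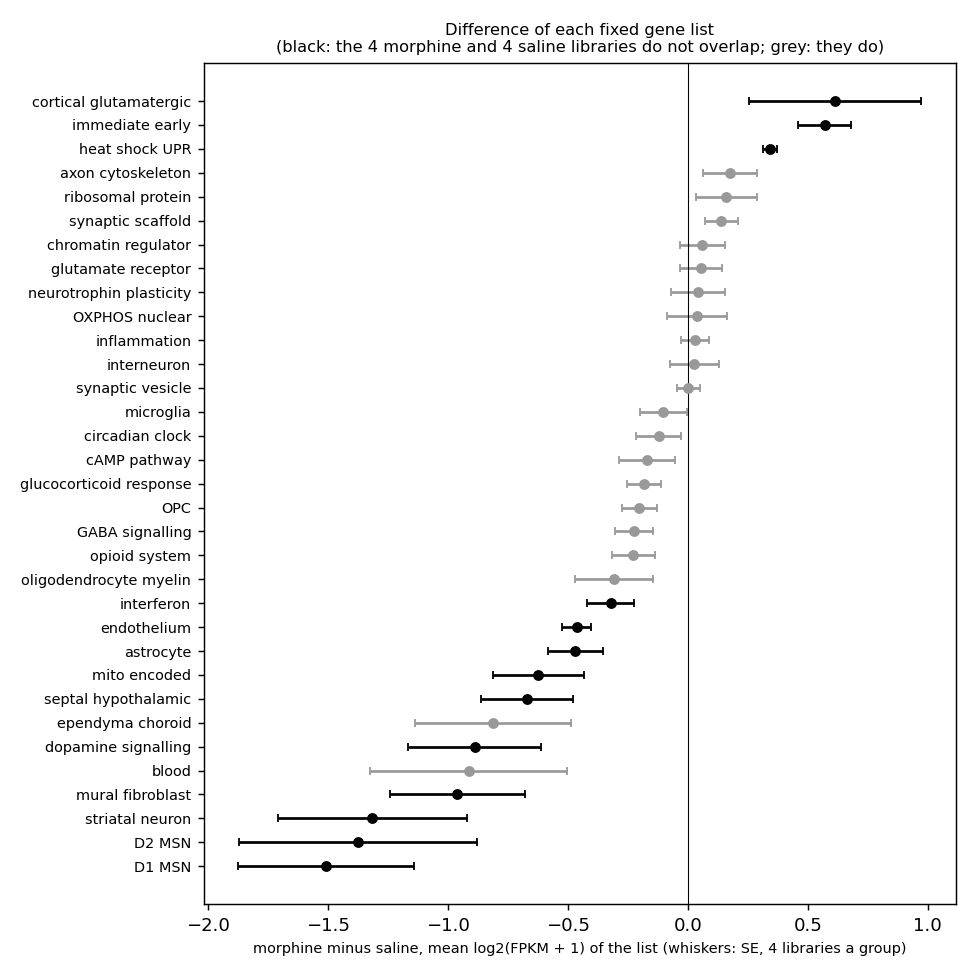
Difference in mean log2(FPKM + 1) between morphine and saline for each of the 33 fixed lists, with SE whiskers over 4 libraries a group. Lists drawn in black, 13 in number, had no overlap between the groups; the heat shock and chaperone list (0.34 ± 0.03) and the endothelial list (−0.46 ± 0.06) had the narrowest errors among them.

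Among the KEGG pathways that the table assigns to genes, fatty acid degradation, retinol metabolism and tryptophan metabolism had the smallest p of those called lower, and ribosome, spliceosome and proteasome of those called higher. Camera called 30 of 321 pathways, 6 higher and 24 lower, and 0 with an estimated correlation (smallest adjusted p = 0.843). The pathways called lower also included complement and coagulation cascades and autoimmune thyroid disease (camera adjusted p = 0.0067 each). Fatty acid degradation had the smallest p (37 genes, 4 fell, median log2 change −0.24, camera adjusted p = 0.000602). Its members Aldh2, Cpt1a, the gate of fatty acid entry into mitochondria, and Eci1 fell by 0.68 ± 0.13, 0.59 ± 0.12 and 0.56 ± 0.11 (log2, SE). In retinol metabolism 2 of 13 genes fell, Cyp2s1 by 0.70 ± 0.13 and Aox1 by 0.61 ± 0.13 (median −0.44, camera adjusted p = 0.00136), and Aldh1a2 did not pass (adjusted p = 0.0706; 0.0119 without saline replicate 4). Tryptophan metabolism held 2 falling genes of 25, Aldh2 and Aox1 (camera adjusted p = 0.00136), and Acat3 did not pass (adjusted p = 0.0885). The pathways called higher were ribosome (0 of 130 passing singly, median 0.16), spliceosome (2 of 130, median 0.12), proteasome (0 of 42, median 0.16), nucleocytoplasmic transport, protein processing in the endoplasmic reticulum (5 of 151 rose) and protein export. In the spliceosome pathway Hspa1a and Pqbp1 rose, the latter by 0.42 ± 0.09. In the proteasome pathway Psmb8, Psme1 and Psmc3 had the smallest p and did not pass (limma adjusted p = 0.0932, 0.0955 and 0.138). Psmb8 was lower with morphine (−0.62 ± 0.18), against the direction of the pathway, and Psme1 and Psmc3 were higher (0.33 ± 0.10 and 0.35 ± 0.12; log2, SE). In the ribosome pathway Mrps6 (0.47 ± 0.13) and Mrpl3, which was lower (−0.31 ± 0.12), did not pass either (limma adjusted p = 0.0804 and 0.182). Genes that fell were enriched in 3 pathways by a one-sided Fisher exact test against 4949 tested and annotated genes: protein digestion and absorption (6 genes, adjusted p = 0.00427), neuroactive ligand-receptor interaction (11 genes, adjusted p = 0.00427) and bile secretion (5 genes, adjusted p = 0.026). Genes that rose were enriched in 0.

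The libraries separated by treatment on the first principal component, which held 41.9% of the variance. That component also followed the mean level of the striatal neuron list over the libraries (r = −0.985), so treatment and striatal marker level are not told apart on it. The morphine libraries lay between 15.8 and 23.2 on it and saline replicates 1, 2 and 4 between −12.8 and −5.5. Saline replicate 3 stood apart at −47.1. Its median correlation with the other saline libraries was 0.961, where the other libraries had between 0.974 and 0.982 within their groups. Saline replicate 4 correlated as well with the morphine libraries (median 0.975) as with the other saline libraries (0.974).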

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

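The tests of correlation between disjoint libraries, of covariates and of mitochondrial removal were chosen after the results they bear on had been seen; the counts over other splits of the libraries were set beforehand. In a group of 4, a library was singled out where its gap to the nearest other library was nearly the whole range (Dixon's test at 95%). Of 246 groups of 4 values examined (named genes, list means and library measures), 19 were singled out, where chance gives about 1 in 20, or 12.3. Of these, 13 were saline replicate 3 and 6 were spread over other libraries.

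Saline replicate 3 stood out high in genes of striatal neurons: Ppp1r1b at 1454.6 FPKM, Scn4b at 124.4, Drd1 at 87.2, Foxp2 at 39.9 and Syndig1l at 11.6. It also stood out high for Ecel1, a marker of septum and hypothalamus, at 39.8 FPKM. It stood out low for Rasl11b, at 18.9 FPKM. Its list means (log2 scale) stood out high for striatal neurons at 6.78, D1 neurons at 5.37 and dopamine signalling at 4.96, and low for cortical glutamatergic neurons at 2.89, axon cytoskeleton at 7.33 and mitochondrially encoded genes at 10.9. In the other libraries, Kcng1 stood out in morphine replicate 3 at 41.1 FPKM and Pdyn in the same library at 3.10. Nfil3 in saline replicate 4 was at 4.01 FPKM, Isl1 in morphine replicate 1 at 0.96, Aox1 in saline replicate 2 at 1.49 and Aldh1a2 in morphine replicate 4 at 1.36.

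Whether the grouping itself could arise by chance was read from all 35 splits of the 8 libraries into groups of 4. The real split called 316 genes with limma and every other split 0 (at most 1469 at an unadjusted p under 0.05, against 2526). So 1 of 35 reached that number, the smallest share these splits allow. That share is under 0.05 for this count taken alone, without adjustment for the other counts read the same way, so it goes against chance but does not exclude it. The 20 lists called by camera were matched by 1 other split (2 of 35, highest other 20), and the 30 KEGG pathways by 1 other split (2 of 35, highest other 36), so chance cannot be excluded for either count. The split that called 36 pathways moved morphine replicate 2 into the saline group in exchange for saline replicate 4. For Gene Ontology terms 13 of 35 splits called at least the 13 terms of the real split (highest other 46). In 18 of the splits each side held 2 saline and 2 morphine libraries and so no treatment contrast. These still called between 4 and 13 lists, 1 and 14 KEGG pathways and 4 and 21 Gene Ontology terms, and 7 of them reached the 13 terms. The cause was not tested.

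The fall of striatal neuron genes with morphine was weighed against the makeup of the tissue pieces. It did not rest on saline replicate 3 alone, since the list median without that library was −0.738 (camera adjusted p = 1.4e-14; SE of the list mean's difference 0.04). A smaller share of striatal and a larger share of cortical tissue in the morphine pieces is a candidate explanation that stays open. Whether it would also lower glial and vessel lists (astrocyte median −0.43) cannot be told here. With the striatal covariate the oligodendrocyte, mural and ependymal lists were no longer called, while the astrocyte and endothelial lists were. With the cortical mean as a covariate the striatal list stayed called (median −0.501, camera adjusted p = 8.97e-09). The D1, D2, oligodendrocyte, mural, astrocyte and endothelial lists stayed called too, and the ependymal list did not (camera adjusted p = 0.0998). The cortical mean does not overlap between the groups, so this covariate cannot exclude a change in tissue share. Across 39 tested striatal, D1 and D2 genes, which are not independent replicates, the gap between saline replicates 3 and 1 correlated with the gap between the morphine mean and saline replicates 2 and 4 at Spearman's rho = −0.651 (permutation p = 2e-05), so the genes that varied most among saline pieces also fell most with morphine. An effect of morphine within the same cells stays open too and cannot be told apart from tissue share here, because a gap of 1.63 in the list's median already separated saline replicate 3 from the other saline libraries and all 4 morphine pieces lie at the low end.

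The rise of chaperone and immediate early genes was weighed against striatal share and mitochondrial share. With the striatal list mean as a covariate the difference in the list mean was 0.306 ± 0.055 (SE) for chaperone genes, before it 0.342 ± 0.031, and 0.905 ± 0.09 for immediate early genes, before it 0.57 ± 0.111, and both lists stayed called. But the striatal mean does not overlap between the groups. Within saline its spread comes mainly from replicate 3 (6.78, against 5.17 to 5.27 in the other saline libraries). This covariate therefore cannot exclude striatal share, which stays open. With mitochondrial genes removed the differences were 0.299 ± 0.034 for chaperone and 0.531 ± 0.124 for immediate early genes, which argues against mitochondrial share as the whole source. Open too are morphine itself, stress or handling before death and the interval to freezing, none of which was tested. With the endothelial mean as a covariate, a measure whose groups do not overlap, the chaperone list was no longer called (median 0.138, before it 0.264), so vessel share stays open for that list.

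The fall of vessel and astrocyte genes was weighed the same way. With the striatal covariate the difference was −0.329 ± 0.087 (SE) for endothelial genes, before it −0.464 ± 0.062, and −0.541 ± 0.209 for astrocyte genes, before it −0.469 ± 0.114. Both lists stayed called, but a covariate whose groups do not overlap cannot exclude striatal share for them. For mural cell and fibroblast genes the difference was −0.295 ± 0.367, before the covariate −0.961 ± 0.281. The call ended because the change shrank and its error grew, so striatal share cannot be told apart from a separate loss of vessel walls or meninges there. With the endothelial mean as a covariate the astrocyte list stayed called (camera adjusted p = 0.000113), but the difference in its mean was −0.582 ± 0.401, an error too wide to tell a smaller vessel share from a separate fall of astrocyte genes. Morphine acting on these cells remains open and untested.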

How the results depend on the processing

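The striatal covariate, the removal of mitochondrial genes and the singling out of saline replicate 3 were chosen after seeing the data. All other settings were set beforehand. The main analysis called 316 genes (130 higher, 186 lower), 20 lists and 30 KEGG pathways, and all 316 genes kept their direction under every setting that tested all of them, except the endothelial covariate (260). Scaling, pseudocounts and a robust fit left between 215 and 311 genes; with quantile normalization 83 were higher. Without a filter on low values 17 genes passed (8 higher, 9 lower) of 19607 tested, and with an FPKM of at least 5 there were 111 lower genes and 14 KEGG pathways. Array weights called 706 (304 higher, 402 lower), an adjusted p under 0.1 gave 865 (390 and 475), and a log2 change of at least 1 left 117 (36 and 81). With mitochondrial genes removed 77 genes were higher. Leaving out 1 library gave between 0 and 450 genes (0 to 198 higher, 0 to 252 lower), between 19 and 22 lists, and between 35.9 and 47.1% of the variance on the first component, which took 59% over the 500 most variable genes; limma called 0 genes without saline replicate 2, morphine replicate 3 or morphine replicate 4 (1953 to 2136 at an unadjusted p under 0.05), with fewer samples in the fit. The replicate numbers did not pair the libraries (correlations of same-numbered libraries 0.052, 0.037, −0.059 and −0.205), and libraries did not all correlate best with their own number; with the replicate block 5 genes passed (2 higher, 3 lower), with 20 lists and 30 KEGG pathways. With an estimated correlation 0 lists and 0 pathways passed, and with fry 6 and 0. Marker covariates removed most gene calls. Genes called were 62 (24 higher, 38 lower) with the cortical mean, 2 (1 and 1) with the striatal mean, and 0 (0 and 0) with the septal, endothelial, mural or ependymal mean (limma, 1256, 726, 587 and 1414 at an unadjusted p under 0.05). Lists and pathways called were 12 and 18 (septal), 13 and 14 (endothelial), 9 and 6 (mural), and 10 and 9 (striatal). They were 17 and 25 with the cortical mean and 15 and 24 with the ependymal mean. Of the 20 lists 9 (septal), 5 (endothelial), 7 (mural), 6 (striatal), 15 (cortical) and 13 (ependymal) kept call and direction. The counts include lists called in the opposite direction: cortical with the septal, endothelial and striatal mean (camera adjusted p = 0.0087, 0.00479 and 8.23e-06), ribosomal with the endothelial and striatal mean (3.22e-10 and 0.0334) and striatal with the endothelial mean (0.0329). Over the 6 covariates the median ratio of the 316 log2 changes to the main ones lay between 0.57 and 0.89, and that of their SE between 1.15 and 3.21. Such a covariate shares part of its differences with the treatment, and the cause of the changes below was not tested. Medians of lists and log2 changes of genes that changed sign were, with the cortical covariate, opioid −0.016, Oprm1 0.207, Oprk1 0.046 and Fkbp5 0.029. With the septal covariate they were ribosomal −0.103, cortical −0.32, D2 0.199, GABA 0.051, cytoskeleton −0.159, Neurod2 −0.071, Gad2 0.214, Oprm1 0.676, Oprk1 0.795 and Fkbp5 0.164. With the endothelial covariate the lists were striatal 0.845, dopamine 0.401, D1 0.068, D2 0.859, ribosomal −0.486, cortical −0.637, blood 0.274, septal 0.227, GABA 0.074 and cytoskeleton −0.149. Its genes were Nr4a2 −0.069, Rasl11b −0.512, Scn4b 0.912, Adora2a 1.271, Pdyn 0.159, Drd1 0.353, Ppp1r1b 0.432, Lrrc10b 0.288, Rasd2 0.084, Syndig1l 0.029, Neurod1 −0.335, Neurod2 −0.885, Ecel1 0.805, Slco1a4 0.01, Gabrd 0.097, Gad2 0.185, Rps15a −0.486, Tubb2a −0.231, Oprm1 2.021, Oprk1 1.9, Drd2 0.869, Fkbp5 1.012 and Psmc3 −0.09. With the mural covariate they were cortical −0.183, blood 0.407, cytoskeleton −0.027, opioid −0.068, Neurod2 −0.237, Kcnj13 0.039, Oprm1 0.076, Oprk1 0.446 and Fkbp5 0.115. With the ependymal covariate they were cortical −0.065, opioid −0.056, Oprm1 0.301, Oprk1 0.554 and Fkbp5 0.037. With the striatal covariate they were dopamine 0.104, ribosomal −0.121, cortical −0.413, D2 0.227, septal 0.021, ependyma 0.062, GABA 0.061, cytoskeleton −0.123, opioid −0.127, Neurod2 −0.413, Gad2 0.07, Oprm1 0.709, Oprk1 0.982, Drd2 0.11 and Fkbp5 0.235. Of the 86 genes and 21 lists run under these settings, no others changed sign; the remaining lists and the genes chosen after their values were seen had no such runs. Depth is unknown, so what depth limits could not be read from these values.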

Other observations

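Some genes in lists that did not pass still changed singly; the genes of this paragraph were chosen after their values were seen. In the circadian clock list (2 of 20 rose, 1 fell; camera adjusted p = 0.414) the repressor Ciart went from 14.7 ± 2.45 to 7.62 ± 1.09 FPKM and Bhlhe40 from 16.6 ± 1.11 to 26.8 ± 3.95 (SD, n = 4 each; limma adjusted p = 0.0264 and 0.035), besides the rise of Nfil3. In the synaptic vesicle list (1 of 24 rose, 2 fell; camera adjusted p = 0.571) Syn1 went from 186.9 ± 22.8 to 303.4 ± 12.6 FPKM and Cplx2 from 268.3 ± 51.5 to 130.2 ± 31.7 (SD, n = 4 each; limma adjusted p = 0.0207 and 0.0265). Chat, which marks cholinergic interneurons, had 8.56 FPKM in saline replicate 3, between 1.65 and 2.21 in the other saline libraries and between 0.10 and 0.38 in the morphine libraries (limma adjusted p = 0.0449), while the interneuron list did not pass (camera adjusted p = 0.854; camera lower, median 0.09). Th, the dopamine synthesis gene, was at 51.0 FPKM in morphine replicate 4 and 16.8 in morphine replicate 2, and between 1.64 and 7.99 in the other 6 libraries (limma adjusted p = 0.592).

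The other lists did not pass. Camera's adjusted p was 0.0665 for synaptic scaffold genes, 0.0769 for microglia and 0.0769 for oligodendrocyte precursors (1 of 11 fell). It was 0.511 for chromatin regulators, 0.571 for glutamate receptors, 0.719 for nuclear genes of oxidative phosphorylation and 0.946 for neurotrophin and plasticity genes (1 of 18 fell). For the cAMP pathway it was 0.773, with a median log2 change of 0.11 and a mean of −0.17. For inflammation it was 0.905, with camera lower, a median of −0.11 and a mean of 0.03. Gene Ontology terms from the table gave 2 of 47 components, 7 of 164 functions and 4 of 142 processes with camera, and 0 of these with an estimated correlation.

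A hypothesis was that tissue share reaches beyond the fixed lists. If the striatal share varies among saline pieces as between the groups, genes lower with morphine should often be highest, among saline libraries, in saline replicate 3, and genes higher with morphine lowest there. In a first test, set up before it was run, this held for 60.2% of the 186 lower genes and 65.4% of the 130 higher genes, but those genes had been called with saline replicate 3 in the fit, so that test decides nothing. A second test, chosen after the first, used genes called without saline replicate 3. That library was the highest saline library for 58.9% of 175 lower genes and the lowest for 59.5% of 121 higher genes, against 31.1% and 29.1% of all genes tested. Calling genes on the other saline libraries favours genes in which those libraries lie close together. Saline replicate 3 then falls outside their range more often than in all genes tested, so the shares of all genes are not a fair expectation. Genes are also not independent. The outcome therefore cannot decide whether a shared axis of tissue makeup runs through the genes called, and any other trait that sets saline replicate 3 apart could give it too. It does not show that morphine had no part in them.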
